A study of Mus musculus with 12 samples.

How the data were processed

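Gene expression was measured by RNA sequencing in 12 libraries of sorted mouse fetal liver cells at E13.5, with 3 libraries for each of LT-HSC controls, LT-HSC mutants, MPP controls and MPP mutants. Per the labels' protocols, red cells were lysed, cells negative for lineage markers were enriched with magnetic beads, 500 to 1000 LT-HSC or 20000 MPP were sorted into extraction buffer, and libraries were made from 10 ng of RNA with a low-input kit that does not keep the strand. Reads from a gene and from an antisense gene at the same place therefore cannot be told apart. Per the submitters' processing notes, reads were processed with STAR and RSEM on the mm10 genome, and the versions and settings are not given in the sources used here.

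The deposited tables, 1 per sample, hold RSEM's expected counts per gene, per the file headers. Expected counts are estimates that share a read between genes or copies it fits, and between 7.13% and 7.76% of the values were fractional. Each table has 24054 genes. They were matched to RefSeq's annotation of GRCm38 by transcript accession (23763 genes) or otherwise by symbol (23949 in all), which gave the coordinates and biotypes. No mitochondrially encoded gene is among the genes of the tables, so the list of such genes (0 members) gave no check of RNA quality. The total per library lay between 10119416 and 14113198, and the 50 highest genes took 9.04% to 11.7% of it. With these depths, 3 counts over a group of 3 libraries served as the floor for a group at 0. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

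Groups and replicate numbers were taken from the titles and genotype labels. Expected counts were rounded to whole numbers and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) after TMM scaling and the filterByExpr filter by group (minimum count 10, minimum total 15), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The genotype was tested in the 6 LT-HSC and in the 6 MPP libraries separately, the cell type in the 6 control libraries, and the difference of the genotype effects as an interaction over all 12 libraries. CPM values come from edgeR's cpm function with the TMM-scaled library size. The components of variance were computed on log2 CPM with a prior count of 2.

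Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and again with the correlation estimated per list, and with adjustment over the lists of a comparison that had at least 3 tested genes. The lists were also tested with fry, which asks whether the members change at all, not whether they change more than other genes. Members were also counted by the adjusted p over all genes and adjusted over the list alone. The 25 lists were histone H3 lysine 9 methylation and HUSH machinery, germline, clustered protocadherins, zinc finger genes with Zfp symbols, gluconeogenesis, glycolysis, interferon-stimulated, stem cell (HSC), fetal HSC program, erythroid (red cell), megakaryocyte, granulocyte and monocyte, lymphoid, mast cell and basophil, hepatoblast, macrophage, endothelial, stromal, neuronal, muscle, epithelial, cell cycle, p53 target, immediate early and heat shock, and mitochondrially encoded genes. In every list called, the median, the mean and the test had the same sign. They differed in sign in some lists that were not called, such as epithelial genes in MPP (median -0.21, mean 1.33) and granulocyte and monocyte genes in MPP (median 0.25, mean -0.06). In the 3 comparisons of groups, no list's median changed when genes at 0 counts in a group were set at their bound.

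The genes named in the text follow a rule. Setdb1 comes first. For each comparison of groups, the rule takes the 10 higher and 10 lower genes with the smallest p among those with an adjusted p under 0.05, a log2 fold change of at least 1 in either direction, no overlap between the samples of the groups and a mean of at least 10 CPM in the higher group. For the interaction it takes the 10 with the smallest p, without the condition on overlap. Placeholder symbols, pseudogenes and genes that mark sex are passed over. Up to 4 called members with the smallest p are named per list, and the 6 genes with the highest mean are named among those switched on. Values of members that did not pass, and the pairs of neighbouring genes given later, were chosen after their values were seen. The lists, the rule, the tests and most alternatives were fixed before the data were examined.

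Titles number the replicates 1 to 3 in every group. Same-numbered LT-HSC controls and mutants deviated together from their group means (r across genes 0.17, 0.195 and 0.315). Deviations from a mean of 3 libraries are not independent, and few matchings are possible. This does not show that the numbers pair the LT-HSC libraries, and no label says what a number stands for. Same-numbered MPP controls and mutants did not deviate together (r = -0.0407, -0.26 and -0.169), nor did all same-numbered control LT-HSC and MPP libraries (r = 0.118, -0.337 and 0.132). The number in the title is not 1 animal, since LT-HSC control 2 is male and MPP control 2 female. The sample numbers within the names of the deposited tables differ from those in the titles, and libraries of both cell types that share such a number had r = 0.202, 0.15, 0.218 and 0.207, which leaves open that these came from 1 fetus each.

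The code was tested on simulated data with 200 genes changed, drawn with the means, library sizes and dispersions of the real counts. They recovered 54.6% of 2-fold and 85.7% of 4-fold changes in LT-HSC, 85.9% and 99% in MPP, 26.5% and 72.7% for the interaction, and 79.6% and 97% between control cell types, with 13 false calls of 150, 13 of 196, 5 of 103 and 8 of 182. A simulated list of 30 shifted genes was found in each comparison, with 0 false lists of 24. The simulated genes varied independently, unlike real lists such as hepatoblast genes in LT-HSC (estimated correlation 0.9565). The simulation therefore gives no rate of false lists for genes that move together. The alternatives were other scalings, no filter or a stricter filter (1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, unrounded counts, a 2-fold limit, sex as a covariate, all 12 libraries in a joint fit, only Cre-positive controls, a shared animal from the names of the tables, and leaving out each library in turn. The summed hepatoblast or macrophage genes as a covariate were added after the data were seen.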

Results

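RNA was sequenced from haematopoietic stem and progenitor cells of mouse fetal liver at E13.5, in fetuses labelled as Setdb1 mutants and in controls. Setdb1 encodes a methyltransferase that places methyl groups on lysine 9 of histone H3, a mark of silenced chromatin, and vav-cre is a Cre recombinase transgene active in blood cells. Cells carrying the LSK markers of early blood cells were sorted into LT-HSC (long-term haematopoietic stem cells, CD150 positive and CD48 negative) and MPP (multipotent progenitors, CD150 negative and CD48 positive). There were 12 libraries, 3 for each combination of cell type and genotype. The mutants carried Setdb1 p/p;vav-cre, and the labels do not define the p allele. Of the controls, LT-HSC control 1 and MPP controls 1 and 2 were Setdb1 +/p without the transgene, and LT-HSC controls 2 and 3 and MPP control 3 were Setdb1 +/p with it. The labels give 500 to 1000 sorted cells per LT-HSC sample and 20000 per MPP sample.

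The total expected count per library lay between 10119416 and 14113198, and between 14863 and 15780 genes had a value above 0. No 2 replicates of a group matched within sampling noise (chi-square per gene between 5.01 and 47.2), so none looked like 1 library deposited again, which does not show that they are separate animals. The 3 LT-HSC mutants were the most unlike each other, with pairwise values of 24.8, 34.2 and 47.2. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may in part be technical. Y-linked and Xist transcripts marked LT-HSC control 2, MPP control 3 and MPP mutant 2 as male. The male MPP mutant 2 also held Xist at 4.44 CPM (counts per 1e6 counts) beside Ddx3y at 112.6 CPM, against Xist at 0.515 and 0.413 CPM in the other male libraries. The ribosomal RNA precursor Rn45s took 0.388% to 0.586% of the counts in LT-HSC, 0.656% to 0.88% in MPP controls and 1.06% to 1.16% in MPP mutants.

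**Figure D1:**
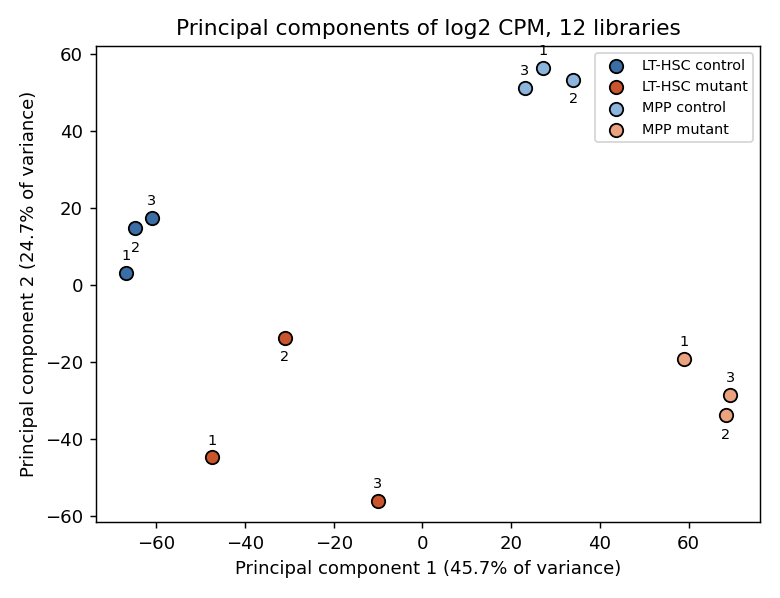
Principal components 1 (45.7% of the variance) and 2 (24.7%) of log2 CPM in the 12 libraries, with each point a library, colours for the 4 groups and numbers for replicates. LT-HSC and MPP controls lie apart on component 1, the MPP mutants lie together, and the LT-HSC mutants spread from -47.4 to -10 on component 1.

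Setdb1 itself, on chromosome 3 from 95323525 to 95357202 in GRCm38, was present in every library. In LT-HSC it stood at 83.9, 73.4 and 108 CPM in controls 1, 2 and 3 and at 66.4, 66.4 and 80.8 CPM in mutants 1, 2 and 3. In MPP it stood at 140, 95.2 and 87.8 CPM in the controls and at 86.9, 117 and 99.0 CPM in the mutants. The log2 fold change of mutant over control was -0.27 (SE 0.165) in LT-HSC, from 88.4 ± 17.8 to 71.2 ± 8.29 CPM (SD, n = 3), and -0.12 (SE 0.167) in MPP, from 107.7 ± 28.3 to 101 ± 15.1 CPM (SD, n = 3). Neither passed edgeR's quasi-likelihood test (adjusted p = 0.651 and 0.598). For all 3 numbers, Setdb1 was lower in the LT-HSC mutant than in the same-numbered control, but the numbers are not shown to pair the libraries. With the replicate number as a block, Setdb1 in LT-HSC mutant vs control had a log2 fold change of -0.2632 (adjusted p = 0.4277). The values are sums over the whole gene, so transcripts that lack some exons still count if the p allele removes them, and the level of Setdb1 does not check the genotype labels here.

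The next comparison asked what differs between mutant and control LT-HSC. Several genes known from germ cells or sperm flagella, low in control LT-HSC, rose in the mutants. Stag3, a cohesin subunit of meiosis, rose from 14.8 ± 2.09 to 155 ± 21.7 CPM (SD, n = 3), and Dnah8, a dynein heavy chain of sperm flagella, from 20.8 ± 0.529 to 136 ± 13.3 CPM (SD, n = 3). Car1, a carbonic anhydrase of red cells, rose from 7.89 ± 2.05 to 796 ± 503 CPM (SD, n = 3). Among the genes that fell were Igf1, a growth factor, from 50.4 ± 5.96 to 11.0 ± 3.05 CPM, and Flt3, a receptor of lymphoid and multipotent progenitors, from 140 ± 8.95 to 65.2 ± 13.1 CPM (SD, n = 3 each). The imprinted neighbours Igf2 and H19 fell from 169 ± 21.2 to 35.6 ± 16.1 CPM and from 182 ± 40.3 to 53.7 ± 13.3 CPM (SD, n = 3 each).

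Of 12847 genes tested in LT-HSC, 54 passed edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 33 higher and 21 lower in the mutants, and 50 of these changed at least 2-fold (30 higher, 20 lower). At an unadjusted p under 0.05 there were 1221 genes. The 10 higher genes named by the rule were Dnah8 (log2 fold change 2.75, SE 0.115, adjusted p = 0.000158), Stag3 (3.43, SE 0.16, adjusted p = 0.00016), Iqcg (4.20), M1ap (3.61), Trap1a (8.14), Tmem150c, Akap5 (4.34), Car1 (6.70, SE 0.526, adjusted p = 0.00201), Tex19.1 and Gstp1 (1.70). M1ap and Iqcg are known from meiosis and sperm flagella, and Tex19.1 from germ cells. Reads of Gstp1 and its near copy Gstp2 cannot be fully told apart, so the size of the Gstp1 change is uncertain. Its call was lost without LT-HSC control 1 or control 3 and with either covariate described next, while Tex19.1 lost its call without control 2. The 10 lower genes were Muc6 (log2 fold change -3.22, SE 0.329, adjusted p = 0.0103), Igf1 (-2.16), Ces2b (-2.45), H19 (-1.73), Plbd1 (-3.64), Flt3 (-1.07), Fcgrt (-1.35), Tmem26 (-2.31), Igf2 (-2.21) and Clec1b (-3.09, SE 0.452, adjusted p = 0.0456). The samples of the groups did not overlap in any of these 20 genes, which the rule required and which chance gives for 10% of genes with 3 against 3.

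The count depended on single libraries. It was 14, 15 and 13 without LT-HSC control 1, 2 and 3, 17 without mutant 1, 102 without mutant 2, and 15 with sex as a covariate, a setting in which the only male LT-HSC library no longer informs the contrast. Every one of the 10 lower genes lost its call when LT-HSC control 1 or control 3 or mutant 1 was left out. They also lost it with the summed hepatoblast or the summed macrophage genes as a covariate, 2 settings added after the data were seen, which left 15 and 23 genes. The folds of all 10 stayed negative with both. In proportion the hepatoblast covariate moved Igf2 in LT-HSC mutant vs control most, to -1.413 (adjusted p = 0.2676), and the macrophage covariate moved Clec1b in LT-HSC mutant vs control most, to -2.317 (adjusted p = 0.1115). Over the 21 lower genes, the hepatoblast covariate moved the median fold from -2.45 to -2.25 and raised the median SE from 0.329 to 0.481.

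Of the 24 gene lists tested in LT-HSC, 4 rose and 9 fell by camera with a preset correlation between genes of 0.01, and 0 passed with the correlation estimated per list. By fry, only germline genes passed (adjusted p = 0.0145). The germline list rose (camera adjusted p = 7.63e-07, adjusted p = 0.181 with an estimated correlation), with a median log2 fold change of 0.92. Of its 10 tested members, 2 passed over all genes, Stag3 and Gm1564 (also named Meioc), and 4 did when adjusted over the list alone. The gluconeogenesis list was not called (camera adjusted p = 0.113), although Fbp2, a fructose-bisphosphatase, was among the genes called. Fbp2 rose from 3 counts over the 3 controls, or 0.066 CPM, to 28.3 ± 18.6 CPM (SD, n = 3), a ratio of 377 with a 95% counting interval from 129 to 1830. Glycolysis rose as a list (adjusted p = 0.00084, and adjusted p = 0.378 with an estimated correlation), with 0 of 16 members called over all genes and 2 adjusted over the list alone. Cell cycle genes rose as a list (adjusted p = 0.00553, and adjusted p = 0.666 with an estimated correlation), with 0 of 32 members called over all genes or adjusted over the list alone. Without LT-HSC control 1 or mutant 2 it was not called. Mast cell and basophil genes, only 3 of them tested, rose as a list (adjusted p = 0.0142, and adjusted p = 0.29 with an estimated correlation), with 0 members called and 1 adjusted over the list alone. That call was lost without mutant 2 and with no filter on low counts.

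The fetal HSC program fell in LT-HSC mutants (camera adjusted p = 0.00084, and adjusted p = 0.378 with an estimated correlation). Of its 11 tested members, H19 and Igf2 were called and 4 passed when adjusted over the list alone. Lymphoid genes fell as a list (adjusted p = 0.00599, and adjusted p = 0.266 with an estimated correlation), with Flt3 the only called member of 10 tested, and 1 adjusted over the list alone. This call was lost without control 1 or without mutant 1. Genes known from haematopoietic stem cells fell as a list (adjusted p = 0.00658, and adjusted p = 0.551 with an estimated correlation), with 0 of 26 members called over all genes or adjusted over the list alone and a median of -0.22. The call was lost without mutant 2 or mutant 3. Megakaryocyte genes also fell as a list (adjusted p = 0.00658, and adjusted p = 0.551 with an estimated correlation), with Clec1b the only called member of 19 and 1 adjusted over the list alone. The list was not called without control 1, control 2 or mutant 3. The p53 target list fell (adjusted p = 0.00658, and adjusted p = 0.266 with an estimated correlation), with a median of -0.16 and 0 of 23 members called over all genes or adjusted over the list alone.

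Markers of other fetal liver cells moved with the genotype in LT-HSC. Hepatoblast genes had a median log2 fold change of -2.78 in the mutants (camera adjusted p = 1.27e-08, and adjusted p = 0.395 with an estimated correlation) and macrophage genes of -1.17 (adjusted p = 1.59e-07, and adjusted p = 0.395 with an estimated correlation). The median was -1.47 for stromal genes (adjusted p = 0.00084, and adjusted p = 0.318 with an estimated correlation) and -0.54 for endothelial genes (adjusted p = 0.00342, and adjusted p = 0.29 with an estimated correlation). No member of these 4 lists was called over all genes, of 17, 16, 5 and 11 tested, and 2, 2, 3 and 2 passed when adjusted over the list alone. Summed over the list, hepatoblast genes stood at 457, 1751 and 1765 CPM in LT-HSC controls 1, 2 and 3 and at 250, 449 and 58.5 CPM in mutants 1, 2 and 3. Macrophage genes summed to 1213, 1483 and 1726 CPM in the controls and to 103, 1518 and 262 CPM in the mutants.

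In MPP, the same question gave far more called genes. Fbp2, close to silent in control MPP, rose from 0.219 ± 0.174 to 249 ± 3.92 CPM (SD, n = 3). Its neighbour Fbp1, the other fructose-bisphosphatase of gluconeogenesis, rose from 2.55 ± 0.349 to 65.4 ± 6.55 CPM (SD, n = 3). Red cell genes rose, Car1 from 9.82 ± 0.356 to 1513 ± 370 CPM and Klf1, a transcription factor of red cells, from 88.0 ± 7.60 to 280 ± 61.0 CPM (SD, n = 3 each). Lymphoid genes fell, such as Ccr9, a chemokine receptor of lymphoid cells, from 74.7 ± 14.5 to 2.41 ± 0.706 CPM (SD, n = 3 each). So did Il7r, the receptor of interleukin 7, from 28.1 ± 9.96 to 2.34 ± 1.14 CPM, and the single gene Ccr2, a chemokine receptor of monocytes, from 120 ± 29.3 to 3.13 ± 0.643 CPM (SD, n = 3 each).

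Of 12392 genes tested in MPP, 4337 passed edgeR's quasi-likelihood test after adjustment, 2039 higher and 2298 lower in the mutants, of which 541 and 866 changed at least 2-fold. The balance of directions depended on the method, with 1627 higher and 2719 lower under upper-quartile scaling and 2138 and 2043 by DESeq2. The 10 higher genes were Fbp2 (log2 fold change 10.08, SE 0.2, adjusted p = 1.7e-10), Tmem150c, Car1 (7.24, SE 0.198, adjusted p = 2.07e-09), Fbp1 (4.65), Dnah8 (3.06), M1ap (4.0), Ahsa2 (2.66), Stag3 (3.47), Trap1a (8.71) and Tex19.1. Tex19.1 rose from 0 counts in the 3 controls to 180 ± 41.1 CPM (SD, n = 3), at least 2222-fold against a floor of 3 counts over the control group. The 10 lower genes were Ccr2 (log2 fold change -5.28, SE 0.219, adjusted p = 6.46e-08), Clec7a (-6.61), Rnd3 (-5.60), Ccr9 (-4.98), Id2 (-2.39), Vcam1 (-6.22), Hpgd (-4.82), Pld4 (-2.15), Ctss (-2.69) and Ctsh (-3.62). Clec7a is a receptor of myeloid cells, Id2 an inhibitor of transcription factors, and Ctss and Ctsh are cathepsins. None of these 20 genes overlapped between the groups, which the rule required and which chance gives for 10% of genes. The count of called genes was 2774 without MPP mutant 2 and 2867 without mutant 3. With only the controls that carry the Cre transgene, 1 MPP control is left, and a joint fit over the remaining libraries of both cell types, whose other groups supply the spread, called 125. The joint fit of all 12 libraries called 2792. The count was 15 with the macrophage sum as a covariate, a setting added after the data were seen in which the covariate follows the genotype closely. Of the 20 named genes, 10 lost their call with the macrophage covariate, and Ccr9, Vcam1 and Ctss also did with only the Cre-positive controls.

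**Figure D2:**
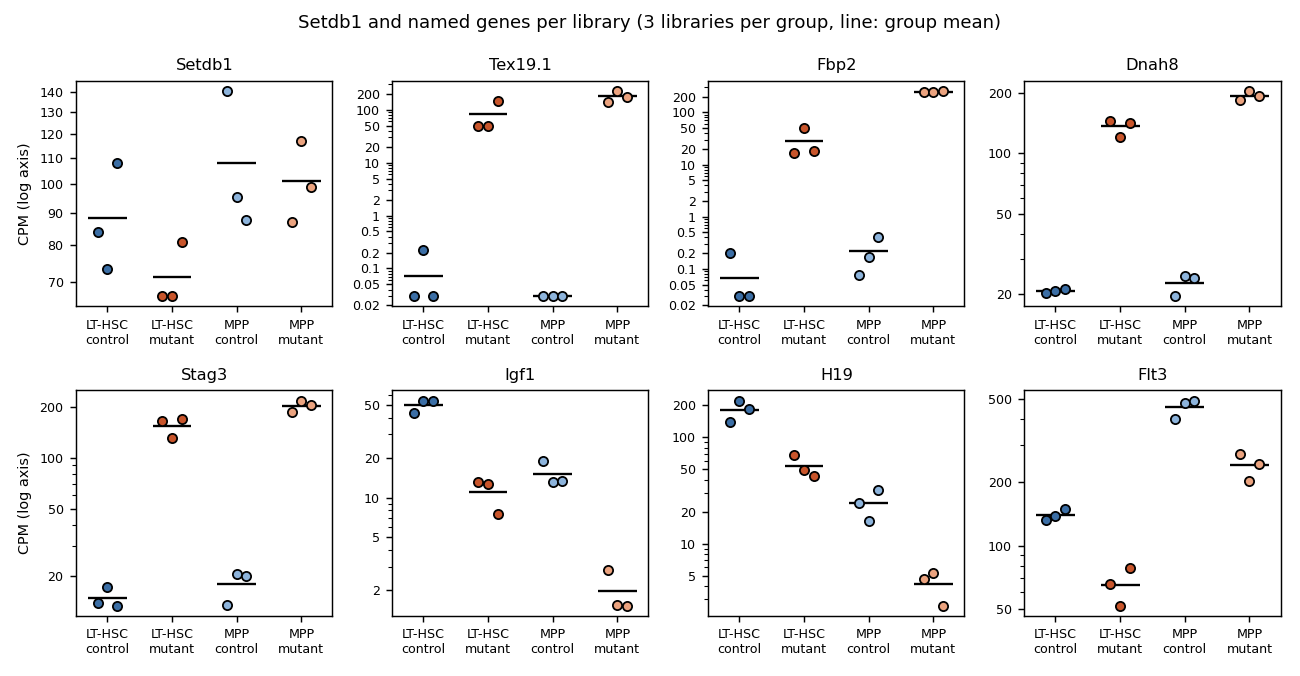
CPM on log axes of Setdb1 and 7 of the named genes in each library, with colours for the 4 groups and a line at the group mean, and values under 0.03 CPM drawn at 0.03. Setdb1 overlaps between genotypes in MPP and in LT-HSC, although each LT-HSC mutant lies below the control of its number, while Tex19.1, Fbp2, Dnah8 and Stag3 lie higher and Igf1, H19 and Flt3 lower in all 3 mutants of both cell types.

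Of the 23 lists tested in MPP, 5 rose and 5 fell by camera, and 0 passed with the correlation estimated per list. By fry, all of these called lists passed except hepatoblast genes (adjusted p = 0.107), and some lists not called by camera passed too. Red cell genes rose (camera adjusted p = 3.91e-10, and adjusted p = 0.444 with an estimated correlation), with 20 of 23 tested members called higher, 0 lower, a median log2 fold change of 1.52 and 20 higher when adjusted over the list alone. Examples were Car1, Epb4.2, a protein of the red cell membrane skeleton (2.14), Tspo2 (2.36) and Klf1 (1.64). Germline genes rose (adjusted p = 7.74e-06, and adjusted p = 0.444 with an estimated correlation), with 7 of 12 members higher, 9 adjusted over the list alone, and a median of 3.01. Among them were Stag3, Tdrd9 (3.82) and Xlr3a (3.87), which has near copies on the X chromosome that may share its reads. Gluconeogenesis rose as a list (adjusted p = 0.0468, and adjusted p = 0.444 with an estimated correlation). Fbp2 and Fbp1 rose and Pck2 fell (-0.39) among its 5 members, and 3 rose and 1 fell when adjusted over the list alone. This list was not called with the replicate number as a block or without MPP control 3. Glycolysis rose (adjusted p = 0.015, and adjusted p = 0.522 with an estimated correlation) with 5 of 16 members called, among them Hk1, a hexokinase (0.93), and Pfkp (0.58), and 5 adjusted over the list alone, but was not called without MPP control 2. Cell cycle genes rose (adjusted p = 0.00081, and adjusted p = 0.522 with an estimated correlation) with 13 of 32 members called, among them Ube2c (0.59) and Plk1 (0.54), and 13 adjusted over the list alone.

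Lymphoid genes fell in MPP mutants (camera adjusted p = 7.52e-09, and adjusted p = 0.444 with an estimated correlation), with 17 of 19 tested members called lower, 0 higher, a median log2 fold change of -1.57 and 17 lower when adjusted over the list alone. Tcf7, a transcription factor of T cells (-4.41), Il7r (-3.61) and Rag1, a recombinase subunit of antigen receptor genes (-3.53), were among them. Interferon-stimulated genes fell (adjusted p = 3.91e-10, and adjusted p = 0.522 with an estimated correlation), with 33 of 39 members lower, 35 adjusted over the list alone, and a median of -1.07. Examples were Zbp1 (-2.67), Ifit3 (-2.67) and Ifi27l2a (-3.43). The fetal HSC program fell (adjusted p = 0.00016, and adjusted p = 0.449 with an estimated correlation), with 8 of 10 members lower and 9 adjusted over the list alone. Among them were Dlk1 (-3.53), H19 (-2.54), Hmga2, a chromatin protein of fetal stem cells (-1.73), and Igf2bp1 (-1.16). In MPP controls 1, 2 and 3, H19 stood at 24.1, 16.4 and 31.8 CPM, in the order of the summed hepatoblast genes (329, 202 and 512 CPM). Hmga2, at 307, 286 and 256 CPM, did not follow that order. Igf2, which also fell in MPP mutants (-2.58), stood at 7.94, 4.9 and 19 CPM in these controls and did follow it. Whether carried-over hepatoblast RNA had a part in the fall of H19, Igf2, Dlk1 or other members in MPP was not tested.

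Macrophage genes were lower in the MPP mutants as well (camera adjusted p = 5.8e-08, and adjusted p = 0.522 with an estimated correlation). Of 16 members, 15 were called lower, also when adjusted over the list alone, and the median was -2.28. Their sum was 1149, 899 and 759 CPM in MPP controls 1, 2 and 3 and 299, 187 and 291 CPM in mutants 1, 2 and 3. Hepatoblast genes were lower (adjusted p = 0.0185, and adjusted p = 0.617 with an estimated correlation), with 7 of 14 members called, 13 adjusted over the list alone, and a median of -2.06. This call was lost without MPP control 1 or control 3. Their sum was 329, 202 and 512 CPM in the controls and 109, 130 and 92.4 CPM in the mutants.

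**Figure D3:**
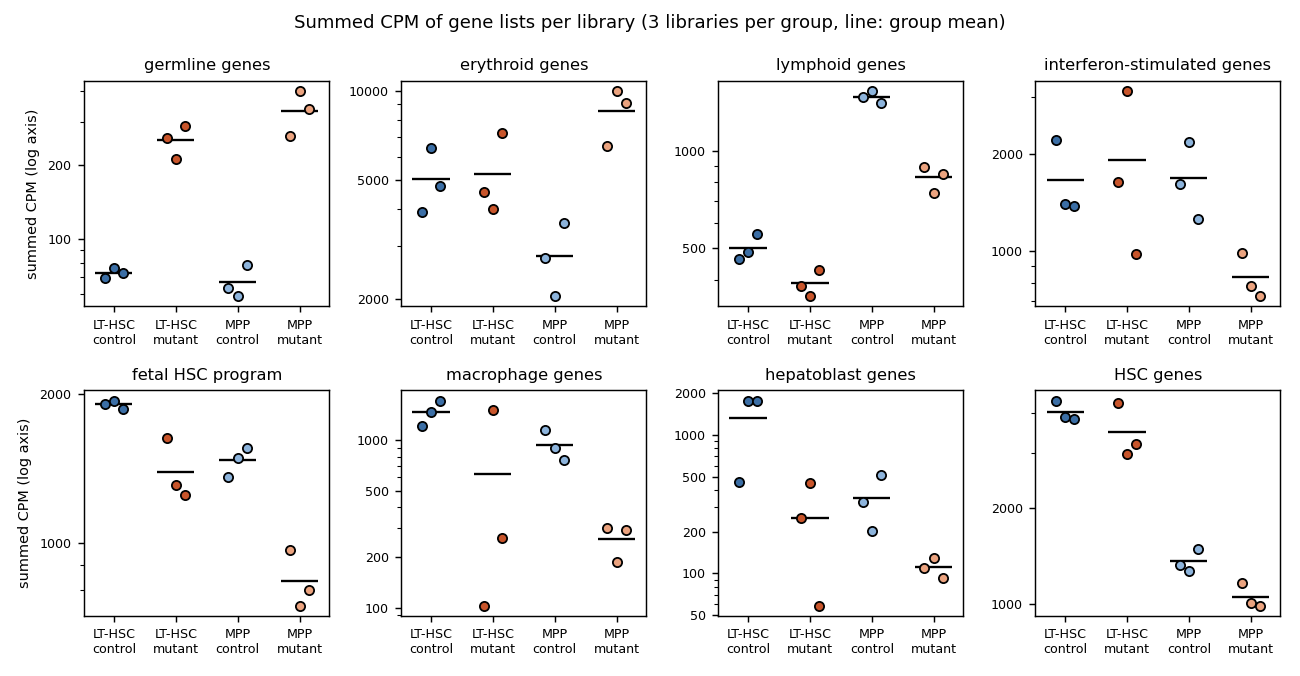
Summed CPM, on log axes, of all genes of 8 lists in each library, with colours for the 4 groups and a line at the group mean. Germline sums are higher in all mutants of both cell types, erythroid sums are higher and lymphoid and interferon-stimulated sums lower in all 3 MPP mutants, and macrophage and hepatoblast sums differ between LT-HSC mutants.

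The same genes were then compared between the cell types. Of the genes tested in both, 12107 in number, 52 were called in LT-HSC, and 49 of these were also called in MPP in the same direction, 31 higher and 18 lower, with 0 in opposite directions. Independent lists of these sizes would share 5.38 higher and 3.43 lower genes. Fisher's exact test (2-sided), which counted genes called in both without regard to direction, gave p = 9.78e-20. The control libraries differed between the cell types, but some fetuses may have given both an LT-HSC and an MPP library. Across all genes tested in both, the log2 fold changes had a Pearson r of 0.711 and a Spearman rho of 0.567, where genes are not independent replicates. Of the MPP calls tested in both, 82.8% (3442 of 4158) had the same sign in LT-HSC. The shared count was 14, 15 and 13 without LT-HSC control 1, 2 and 3, 17 without mutant 1 and 97 without mutant 2.

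**Figure D4:**
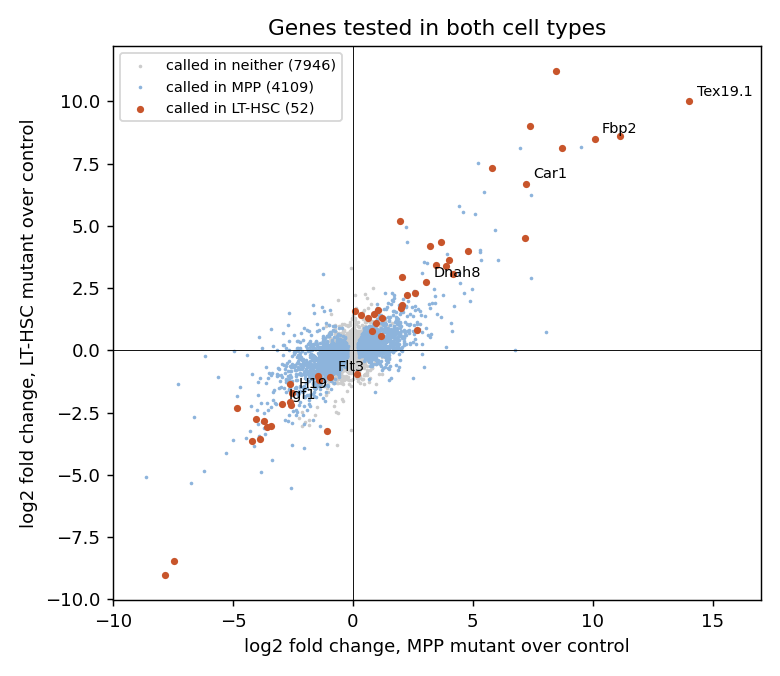
The log2 fold change of mutant over control in MPP (x axis) and in LT-HSC (y axis) of the 12107 genes tested in both, with each point a gene and colours for the 52 genes called in LT-HSC, for further genes called in MPP and for genes called in neither. Among the 52 genes called in LT-HSC, the median ratio of the LT-HSC to the MPP log2 fold change is 0.9, and among the 1235 genes chosen by a 2-fold call in MPP it is 0.359, where each choice favours the cell type it was made in.

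Genes that were silent in controls and present in mutants were counted as those under 0.5 CPM in all 3 controls and at 1 CPM or more in all 3 mutants. There were 18 such genes in LT-HSC, 5 of them called, and 68 in MPP, all 68 called, and 15 were common to both. The reverse count was 20 in LT-HSC, 4 of them called, and 54 in MPP, all called. In LT-HSC the highest were Tex19.1 at 81.0 ± 54.9 CPM, with 3 counts in the controls (ratio 1190, 95% counting interval 407 to 5770), Fbp2, and Gm1564 at 22.4 ± 18.6 CPM with 0 counts in the controls, at least 331-fold higher. Tmem150c followed at 12.8 ± 3.25 CPM with 1 count in the controls (ratio 550, interval 98.2 to 21800). Ak7 and Entpd3 came next at 11.4 ± 11.6 and 5.69 ± 1.78 CPM, which did not pass edgeR's test (adjusted p = 0.0923 and 0.0543) (SD, n = 3 each). In MPP the highest were Fbp2, Tex19.1, Tmem150c at 86.2 ± 0.630 CPM with 1 count in the controls (ratio 3200, interval 574 to 126000). After these came Gm1564 at 32.7 ± 18.5 CPM with 3 counts (ratio 408, interval 139 to 1980), Amotl1 at 25.1 ± 6.44 CPM and Ak7 at 21 ± 8.24 CPM (SD, n = 3 each). These intervals cover counting error only. Without LT-HSC mutant 1 or 2 the LT-HSC count of genes turned on was 32 or 33, and the count turned off was 63 without control 1 and 69 without mutant 2. Leaving out a library can only keep or raise these counts, since the limits apply to every library.

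By annotation, the genes called higher in MPP held a larger share of protein-coding genes than all genes tested, 97.4% against 96.1% (Fisher's exact test, odds ratio 1.67, adjusted p = 0.00344 over 12 tests). They held a smaller share of long non-coding RNAs, 1.77% against 2.79% (odds ratio 0.582, adjusted p = 0.00906). The long non-coding share did not pass without MPP mutant 3. No biotype differed among the LT-HSC calls or the lower MPP calls.

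Whether the mutation acted differently in LT-HSC and MPP was tested directly as an interaction. Lyz2, lysozyme of myeloid cells, fell in MPP from 994 ± 257 to 263 ± 22.2 CPM and stood at 422 ± 53.6 and 468 ± 41.5 CPM in control and mutant LT-HSC (SD, n = 3 each). Irf8, a transcription factor of monocytes and dendritic cells, fell in MPP from 109 ± 17.6 to 37.5 ± 5.51 CPM and stood at 52.2 ± 6.83 and 61.5 ± 7.79 CPM in LT-HSC (SD, n = 3 each). Ahsa2 rose from 65.4 ± 6.54 to 422 ± 40.6 CPM in MPP and stood at 85.0 ± 6.10 and 147 ± 3.22 CPM in control and mutant LT-HSC (SD, n = 3 each). Red cell genes differed as a list by camera with the preset correlation (adjusted p = 1.36e-14), with a median difference of -1.52 between the LT-HSC and the MPP log2 fold change. With an estimated correlation they did not (adjusted p = 0.278), and 1 of 23 members was called.

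Of 13249 genes, 50 passed edgeR's test of the interaction, 30 with a higher and 20 with a lower fold change in LT-HSC than in MPP, and 1637 had an unadjusted p under 0.05. With upper-quartile scaling the split was 30 and 11. The count was 137 with a shared animal, 339 by DESeq2, 470 by limma-voom, 87 with no filter and 11 with sex as a covariate. The difference in log2 fold change was -1.90 for Ahsa2 (adjusted p = 0.000165), 2.07 for Lyz2 (adjusted p = 0.00741), 1.78 for Irf8, 2.87 for Lpar1, 2.31 for Ppfia4, 1.48 for Coro2a, 1.13 for Hmga2, -1.56 for Itsn1, 2.81 for Slfn2 and 1.85 for Padi2 (adjusted p = 0.0259). Of the 24 lists tested, interferon-stimulated genes (camera adjusted p = 2.94e-11, median 1.34), the fetal HSC program (adjusted p = 0.0014, median 0.45) and lymphoid genes (adjusted p = 2.6e-09, median 0.65) had higher, and red cell genes (adjusted p = 1.36e-14) lower fold changes in LT-HSC. With an estimated correlation these had adjusted p = 0.61, 0.441, 0.0627 and 0.278. By fry they had adjusted p = 0.342, 0.164, 0.008 and 0.021. Called members numbered 0 of 39, 1 of 11 (Hmga2), 0 of 19 and 1 of 23 (Trim10, -2.15), and 1, 3, 3 and 18 when adjusted over the list alone. The interferon-stimulated sum in LT-HSC mutants 1, 2 and 3 was 1634, 3117 and 981 CPM, against 985, 782 and 726 CPM in MPP mutants 1, 2 and 3. In controls 1, 2 and 3 the sum was 2207, 1399 and 1378 CPM in LT-HSC and 1614, 2169 and 1255 CPM in MPP. Among the LT-HSC mutants, only mutant 2 lay above all LT-HSC controls, and mutant 3 lay below all of them. The count of interaction genes rested on single libraries, with 15, 11 and 10 genes without LT-HSC control 1, 2 and 3, 17 without LT-HSC mutant 1 and 885 without LT-HSC mutant 3. It was 7, 5 and 14 without MPP control 1, 2 and 3, and 1 and 4 without MPP mutant 2 and 3. Ahsa2 was the only named gene called in all 22 alternatives.

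The control libraries, all Setdb1 +/p, show what separates the sorted cell types without the p/p genotype. LT-HSC controls 2 and 3 but only MPP control 3 carried the Cre transgene. The number of sorted cells also differed, 500 to 1000 against 20000. Neither can be told apart from the cell type here. Genes known from stem cells were higher in LT-HSC, such as Pdzk1ip1 at 137 ± 4.6 against 5.85 ± 1.31 CPM in MPP (SD, n = 3 each). Procr, the endothelial protein C receptor, stood at 144 ± 13.9 against 13.2 ± 2.67 CPM, and Mllt3 at 249 ± 26.8 against 43.9 ± 4.13 CPM (SD, n = 3 each). Genes of lymphoid and myeloid cells were lower in LT-HSC, such as Itgal, an integrin of leukocytes, at 36.6 ± 3.71 against 221 ± 29.1 CPM, and Cd33 at 3 ± 0.542 against 40.8 ± 6.49 CPM (SD, n = 3 each). Cd48, which was part of the sort gate, stood at 14.4 ± 3.23 CPM in LT-HSC and 228 ± 28.0 CPM in MPP (SD, n = 3 each), as the gate requires.

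Of 12834 genes tested between the control cell types, 4942 passed edgeR's test, 2628 higher and 2314 lower in LT-HSC, of which 1236 and 624 differed at least 2-fold. The 10 higher genes were Pdzk1ip1 (log2 fold change 4.55, SE 0.15, adjusted p = 1.96e-07), Esam (2.95), Trpc6 (4.53), Tek (2.61), Tbxas1 (3.04), Hid1 (3.60), Procr (3.45), Ctnnal1 (3.10), Mllt3 (2.51) and Mamdc2 (3.0). The 10 lower genes were Lars2 (-3.41, adjusted p = 1.96e-07), Tespa1 (-4.54), Cd48 (-3.98), Sh2d5, Itgal (-2.59), Cd52 (-2.92), Slc9a9, Stc1 (-6.81), Cd33 (-3.76) and Gpr97 (-3.62). Lars2 stood at 507 ± 60.2 CPM in LT-HSC and 5409 ± 470 CPM in MPP (SD, n = 3 each).

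Of the 24 lists tested between the control cell types, 8 were higher and 4 lower in LT-HSC by camera, and 0 passed with the correlation estimated per list. By fry, all of these called lists passed except hepatoblast (adjusted p = 0.229) and macrophage genes (adjusted p = 0.112), and some lists not called by camera passed too. Stem cell genes were higher (camera adjusted p = 1.49e-12, and adjusted p = 0.217 with an estimated correlation), with 21 of 25 members higher and 1 lower (22 and 1 adjusted over the list alone). Megakaryocyte genes were higher (adjusted p = 1.33e-05, and adjusted p = 0.262 with an estimated correlation), with 15 of 19 members higher and 1 lower (16 and 1 adjusted over the list alone), among them Rab27b (2.95) and Itga2b, a platelet integrin (2.84). Red cell genes were higher (adjusted p = 0.000184, and adjusted p = 0.229 with an estimated correlation), with 16 of 23 members higher and 0 lower (16 adjusted over the list alone), among them Epor, the erythropoietin receptor (1.10). Clustered protocadherins, cell adhesion genes best known from neurons, were higher (adjusted p = 4.32e-05, and adjusted p = 0.217 with an estimated correlation), with 15 of 22 members higher and 0 lower (16 adjusted over the list alone). Among them were Pcdhgc4 (1.91) and Pcdhga5 (1.41), whose shared exons leave their reads uncertain. Epithelial genes (adjusted p = 0.000879, and adjusted p = 0.262 with an estimated correlation) had 6 of 9 members higher (7 adjusted over the list alone), among them Ocln (2.91) and Krt18 (1.71).

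Lymphoid genes were lower in control LT-HSC than in control MPP (camera adjusted p = 2.67e-08, and adjusted p = 0.0867 with an estimated correlation), with 16 of 19 members lower and 1 higher (17 and 1 adjusted over the list alone). These included Rag2 (-6.75), Satb1 (-2.10) and Flt3 (-1.70). Cell cycle genes were lower (adjusted p = 2.75e-05, and adjusted p = 0.299 with an estimated correlation), with 20 of 32 members lower and 0 higher (20 adjusted over the list alone), among them Top2a (-0.74) and Cdk1 (-0.57). Granulocyte and monocyte genes were lower (adjusted p = 0.000724, and adjusted p = 0.299 with an estimated correlation), with 9 of 23 members lower and 1 higher, also when adjusted over the list alone. The lower ones included Cebpa, a transcription factor of myeloid cells (-3.68), and Ly86 (-2.51). Mast cell and basophil genes were lower (adjusted p = 0.00679, and adjusted p = 0.299 with an estimated correlation), with 4 of 6 members lower, also when adjusted over the list alone, among them Cpa3 (-2.31) and Hdc (-1.42).

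Markers of other liver cells also differed between the control cell types. Hepatoblast genes were higher in LT-HSC (camera adjusted p = 0.00843, and adjusted p = 0.668 with an estimated correlation), with 15 of 16 members higher and 1, Hnf4a (-1.79), lower, also when adjusted over the list alone. Macrophage genes were higher (adjusted p = 0.00679, and adjusted p = 0.598 with an estimated correlation), with 10 of 16 members higher and 0 lower, also when adjusted over the list alone, among them Vcam1 (0.78) and C1qc (0.77). Endothelial genes, several of which stem cells also use, were higher (adjusted p = 0.00679, and adjusted p = 0.217 with an estimated correlation), with 6 of 11 members higher and 0 lower, also when adjusted over the list alone. These included Tie1 (2.16) and Kdr (3.55).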

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

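The tests of the 21 lower genes with the hepatoblast sum as a covariate and within genotypes, of the lymphoid and interferon-stimulated genes in control cells, of the slope, of the needed share and of the size of list changes were chosen after the result was seen, and the splits, the hepatoblast profile and the neighbour counts were written down before.

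The interaction test called 50 genes, of which the rule names 10, and 4 lists by camera, none of which passed with an estimated correlation (adjusted p = 0.61, 0.441, 0.0627 and 0.278). By fry, lymphoid genes (adjusted p = 0.008) and erythroid genes (adjusted p = 0.021) passed and the others did not. Lyz2 (difference in log2 fold change 2.07), Irf8 (1.78), Coro2a (1.48) and Padi2 (1.85) fell in MPP mutants, with log2 fold changes of -1.95, -1.57, -1.40 and -1.54, and did not pass in LT-HSC. Lpar1 (2.87), Ppfia4 (2.31) and Slfn2 (2.81) fell in MPP by larger amounts (-3.60, -2.27 and -2.79). Hmga2 (1.13) fell in MPP (-1.73) and had -0.53 in LT-HSC. Ahsa2 (-1.90) and Itsn1 (-1.56) rose in MPP (2.66 and 1.47) and had 0.83 and -0.03 in LT-HSC. The lists were interferon-stimulated genes (median difference 1.34), the fetal HSC program (0.445), lymphoid genes (0.645) and erythroid genes (-1.52).

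The first pattern is the fall of hepatoblast genes and of 21 called genes in LT-HSC mutants. For the hepatoblast genes, carried-over RNA and a change within LT-HSC cannot be told apart, since the lowest correlation of a library's profile with the others was 0.676, in mutant 3 with only 58.5 CPM, against 0.915 to 0.952 in the other libraries. The 21 genes rose with the hepatoblast sum within genotypes by a slope of 0.0951 (95% interval 0.0423 to 0.148), where hepatoblast RNA as the whole cause needs 0.844, and with the macrophage sum by 0.0388 (-0.119 to 0.197), where 1.05 is needed. A call favours genes with little spread within genotypes, which narrows these intervals and lowers the slopes of the 21. Hepatoblast genes, not chosen by a call, had slopes with quartiles 1.06 and 1.58 against 0.0411 and 0.169 for the 21 (highest 0.34, with 2 of 17 hepatoblast genes no higher). Macrophage genes had 0.912 and 1.15 against -0.00818 and 0.0752. Each gene of a list was set against the sum of the other genes of that list, which favours high slopes. The contrast therefore cannot weigh against either RNA as the whole cause. With the hepatoblast covariate all 21 calls ended. The median log2 fold change went only from -2.45 to -2.25 (quartiles -3.22 and -1.73 before, -2.95 and -1.41 after), and the median SE rose from 0.329 to 0.481. Carried-over RNA, as the whole or a part of the cause, and a change within LT-HSC stay open.

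The second pattern is the fall of lymphoid and interferon-stimulated genes in MPP mutants, where macrophage genes fell as well. If macrophage RNA carried the lymphoid genes, they should be higher in LT-HSC controls, whose macrophage sum was higher than that of MPP controls by 0.655 on the log2 scale. Their median log2 ratio was instead -2.23, with 16 of 17 genes lower in LT-HSC controls, which argues against that explanation. For interferon-stimulated genes the ratio was -0.05, so macrophage RNA cannot be told apart from a change within MPP. Fewer lymphoid-primed cells within the sorted gate remain possible and were not tested.

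The third pattern is the smaller size of changes in LT-HSC. Of the 23 lists fixed in advance, with members tested in both cell types, 18 changed less in LT-HSC. Of them 1, gluconeogenesis, passed with the error between libraries (1.37 against 2.58 on the log2 scale, adjusted p = 0.0228), but Fbp2 and Fbp1 carry these means. The interaction of its 5 genes did not pass camera (adjusted p = 0.0618, and adjusted p = 0.349 with an estimated correlation, 0 members called) but passed fry (adjusted p = 0.021). Red cell genes changed by 0.0639 against 1.68 (difference -1.62, SE 0.384, adjusted p = 0.054 with the error between libraries). Their interaction passed fry (adjusted p = 0.021) but not camera with an estimated correlation (adjusted p = 0.278). While 0 of 23 members had a higher fold change in LT-HSC, the members moved together (estimated correlation 0.42) and are not independent. Lymphoid genes (-0.511 against -1.11, adjusted p = 0.054, and 0.0151 in a first run with members near the floor) passed fry too (adjusted p = 0.008), also with members near the floor. For gluconeogenesis, red cell genes, lymphoid genes and the remaining lists, equal effects hidden by the spread and a difference of the cell types cannot be told apart, since 3 libraries per group are few. Sets chosen by a call decide nothing, since the highest slope of 0.701 over 2-fold MPP calls favours smaller and the median ratio of 0.9 over the 52 LT-HSC calls favours larger LT-HSC changes. The median needed share of affected cells, 0.0266 for 20 called erythroid genes against 0.454 for 15 genes switched on in both cell types, comes from chosen genes too and leaves control-like cells open.

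Regrouping the libraries gave 1 of 10 splits with as many called genes as the real groups in LT-HSC (54 genes, highest other 0), 1 of 10 in MPP (4337, highest other 1) and 1 of 10 between control cell types (4942, highest other 0), and in each case the 1 is the real grouping. With 10 splits there are too few for a share under 0.05. For the interaction, 5 of 60 drawn splits gave as many genes as the real 50, the real one among the 5, with 2287 as the highest other. All 5 lie among the 7 splits that kept the MPP groups whole, and the other 53 gave 0 genes each. The large counts thus carry the MPP genotype effect and point to a structure of the samples. For that reason the share cannot weigh for or against chance for the count of 50.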

How the results depend on the processing

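The counts of called genes in LT-HSC, in MPP and for the interaction all depended on the choices made. Of the settings varied here, the hepatoblast and macrophage covariates were chosen after seeing the data and the others before. Over all alternatives, 143 comparison results stayed the same, 59 moved by more than 1.5-fold and 4 weakened; 1208 values of named genes stayed the same, 130 weakened and 0 reversed, where a change of sign counts as reversed only if the gene was called before or after, so that 4 sign changes of Setdb1, never called, are among the 1208. The cause of a shift was not tested unless stated.

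The 54 LT-HSC genes became 260 with DESeq2, 88 with limma-voom, 250 with all 12 libraries in a joint fit, 15 with sex and 15 with the hepatoblast and 23 with the macrophage covariate, and 13 to 102 with a library left out (14, 15 and 13 without control 1, 2 and 3, 17 and 102 without mutant 1 and 2). Sex gave 15 genes, the same number as leaving out control 2, the only male LT-HSC library. The 4337 MPP genes became 1407 with a 2-fold limit, 2792 with all 12 libraries, 125 with Cre-positive controls (a joint fit over both cell types with 1 MPP control left), 15 with the macrophage and 786 with the hepatoblast covariate, and 2774 to 4756 with a library left out (2774 and 2867 without mutant 2 and 3). The 50 interaction genes became 87 with no filter, 339 with DESeq2, 470 with limma-voom, 11 with sex, 137 with a shared animal, and 1 to 885 with a library left out (15, 11 and 10 without LT-HSC control 1, 2 and 3, 17 and 885 without LT-HSC mutant 1 and 3, 7, 5 and 14 without MPP control 1, 2 and 3, 1 and 4 without MPP mutant 2 and 3). The 2039 higher and 2298 lower MPP genes became 1627 and 2719 with upper-quartile scaling, 2138 and 2043 with DESeq2, and 1439 and 1353 in the joint fit. Setdb1 in MPP mutant vs control, never called, turned from -0.1223 to 0.05648 with limma-voom, 0.1179 without MPP control 1, 0.1384 with Cre-positive controls and 0.1749 with the macrophage covariate. The 4942 control cell type genes became 1860 with a 2-fold limit and 3410 to 4873 with a library left out.

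The 49 shared genes became 197 with DESeq2, 78 with limma-voom, 15 with sex, 203 with all 12 libraries, 15 with the hepatoblast and 9 with the macrophage covariate, and 13 to 97 with a library left out (14, 15 and 13 without LT-HSC control 1, 2 and 3, 17 and 97 without LT-HSC mutant 1 and 2). For the result on gene biotypes: lncRNA among higher calls in MPP, odds ratio 0.582, the value was 0.5809 with Cre-positive controls, 0 with the macrophage and 0.7726 with the hepatoblast covariate, none of which passed, and 0.495 to 0.7133 with a library left out, where 0.7133 without MPP mutant 3 did not pass. With CPM limits of 0.25 and 2 the genes switched on fell from 18 to 5 in LT-HSC and from 68 to 25 in MPP, and those switched off from 20 to 2 and from 54 to 9. With a library left out these 4 counts were 19 to 33 (32 and 33 without LT-HSC mutant 1 and 2), 71 to 98, 26 to 69 (63 without LT-HSC control 1, 69 without LT-HSC mutant 2) and 61 to 76. By the rule itself, stricter limits can only keep or lower these counts, and leaving out a library can only keep or raise them.

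With the correlation estimated per list, 0 lists were called, against 13 in LT-HSC, 10 in MPP, 4 for the interaction and 12 between control cell types. With a library left out the counts were 10 to 14, 9 to 13, 4 to 8 (7 and 8 without LT-HSC mutant 1 and 2) and 12 to 13. The mast cell and basophil list in LT-HSC reversed with no filter (adjusted p = 0.996). With the replicate number as a block, gluconeogenesis in MPP mutant vs control was lost (adjusted p = 0.05135), LT-HSC had 48 genes, MPP 3765, the interaction 53 and the control cell types 4881, and no other named gene or list lost its call with the block.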

Other observations

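Among lists that were not called, the H3K9 and HUSH silencing machinery was mixed in MPP mutants (camera adjusted p = 0.352, and adjusted p = 0.522 with an estimated correlation), with 4 of 21 members higher and 2 lower, also when adjusted over the list alone. Fam208a and Morc2a of the HUSH pathway rose (log2 fold change 1.08 and 0.77) and Dnmt3a, a DNA methyltransferase, fell (-0.86). In LT-HSC the list was not called (adjusted p = 0.0585), with 0 of 21 members called and 2 adjusted over the list alone. Protocadherins were mixed in MPP (adjusted p = 0.952), with 5 of 17 members higher and 4 lower, and not called in LT-HSC (adjusted p = 0.496, 0 of 28). Zinc finger genes had 28 higher and 42 lower of 317 in MPP (adjusted p = 0.156) and 1 higher of 325 in LT-HSC (adjusted p = 0.812). Immediate early and heat shock genes had 3 higher and 7 lower of 16 in MPP (adjusted p = 0.128), among the lower Jun (-1.45), Fos (-1.83) and Atf3 (-2.77), and 1 lower of 15, Jun (-1.01), in LT-HSC (adjusted p = 0.832).

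In MPP mutants, stem cell genes were not called as a list (camera adjusted p = 0.0847, 2 higher and 7 lower of 23), nor were megakaryocyte genes (adjusted p = 0.0529, 1 higher and 7 lower of 17), granulocyte and monocyte genes (adjusted p = 0.952, 7 higher and 8 lower of 23), mast cell and basophil genes (adjusted p = 0.732, 2 higher and 2 lower of 6), endothelial genes (adjusted p = 0.11, 2 higher and 6 lower of 10), epithelial genes (adjusted p = 0.511, 2 higher of 6), neuronal genes (adjusted p = 0.237, 2 lower of 4), muscle genes (adjusted p = 0.156, 1 higher and 3 lower of 6) or p53 targets (adjusted p = 0.561, 2 higher and 4 lower of 21). In LT-HSC mutants, erythroid genes (adjusted p = 0.792, 1 of 23, Car1, higher), interferon-stimulated genes (adjusted p = 0.83, 0 of 39), neuronal (adjusted p = 0.487, 0 of 5), muscle (adjusted p = 0.556, 0 of 4) and epithelial genes (adjusted p = 0.188, 0 of 9) were not called.

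Genes that changed at least 2-fold in MPP mutants lay next to each other on chromosomes more often than random sets. The higher genes gave 68 neighbouring pairs against a mean of 23.6 in 10000 permutations (highest 41), and the lower genes 160 against 60.1 (highest 86), each with p = 1e-04, the smallest possible value. Fbp2 (from 62836884 to 62858400) and Fbp1 (from 62864753 to 62888298) on chromosome 13 form such a pair. Both directions clustered, and near copies such as Gstp1 and Gstp2 may add pairs through shared reads, which was not tested. The 68 pairs may thus reflect domains of released silencing, shared reads, or the ordinary clustering of related genes. Measuring H3K9 methylation at Fbp2, Fbp1 and Tex19.1 in sorted MPP of both genotypes would test the first at these loci, but would not decide for all 68 pairs.

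If the lymphoid fall, with a ratio of -2.23 in control cells, reflects fewer lymphoid-primed cells, single-cell RNA sequencing of the MPP gate should show a smaller Flt3-high fraction with unchanged levels per cell. With the hepatoblast covariate, Igf2 in LT-HSC mutant vs control had -1.413 (adjusted p = 0.2676) and H19 in LT-HSC mutant vs control -1.244 (adjusted p = 0.4377), against a median of -2.25 for the 21 genes. If the fall of Igf2 and H19 lies within the stem cells, it may persist after a second sort that removes hepatoblasts.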
